A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

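Total RNA of 3 biofilm and 3 bottom layer samples of an S. cerevisiae strain was labelled with biotin as amplified RNA and hybridised to an Affymetrix yeast array, per the labels' protocols. The deposited values are linear signal intensities, 1 per probe set and array, and MAS5 is named in the submitters' processing notes; its version, its background settings and detection calls are not given in the sources used here. The deposited intensities hold 9335 probe sets per array, run from near 0 to 37322, and have a mean of about 500 on each array once the lowest and highest 2% are set aside, so arrays had been scaled to a common mean. A sample whose RNA is spread over fewer genes is shifted by such scaling, and signals at the low end are mostly background.

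Probe sets were named through a platform table, with symbols taken by gene identifier from a gene table of the assembly R64, used for names only. Of the 9335 probe sets 60 were controls, 6504 paired with exactly 1 gene, 328 with several genes and 2443 were not listed; the last 2 kinds were not named. Values were taken as log2(signal + 16), so that folds of dim genes are understated. For each of 5656 genes the probe set with the highest mean over the 6 arrays was kept, and the dimmest 25% of genes by that mean, 1414 genes, were left out, leaving 4242. As an empirical background, the highest of 19 control probe sets for mouse and Bacillus subtilis genes that were taken as not spiked was read on each array; where a gene lay below it on all 3 arrays of one group, a fold was given as a bound, with that level in place of the gene's own signal.

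The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05), without a replicate block. Values are means ± SD of the linear signal over the 3 arrays of a group, and folds and log2 fold changes come from the fit. The 12 genes with the largest change in each direction were named among genes past the threshold whose groups did not overlap and whose mean in the higher group reached the median of the genes tested; FLO11, LEU2, LYS2 and URA3 were always named, with up to 4 members of a list by smallest p. In the report the a-specific genes MFA1, MFA2, AGA2 and STE6 were named outside this rule, after their values were seen. These rules, 36 gene lists and the alternatives were fixed before the data were examined, except where the closing section says otherwise.

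Gene lists with at least 4 members tested, 34 of the 36, were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. The preset gives 18 calls, 6 higher and 12 lower. With an estimated correlation 0 lists are called by camera (lowest adjusted p = 0.178, with 8 lists at an unadjusted p below 0.05). Fry, which asks only whether a list's genes move one way on balance, calls 27, among them these 18. For hypoxic and G1/S genes the estimated correlations were -0.0663 and -0.0466, below the preset, and the calls were lost all the same. More correlation between genes than the preset therefore does not account for these losses. A lost call does not show that a list is unchanged. Counts of members use the adjustment over all genes; adjusted over the list alone 59 in place of 58 cytosolic ribosomal protein genes, 36 in place of 34 amino acid synthesis genes and 5 in place of 6 phospholipid synthesis genes were higher. For the respiratory chain 18 in place of 19 were lower, for trehalose and glycogen 16 in place of 14 lower and 2 in place of 1 higher, and for the proteasome 3 in place of 4 lower and 6 in place of 7 higher. Counts of the other lists were equal.

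Single values per array were compared by exact two-sided permutation over the 20 labellings. The fit was tested on simulated data with the real means and spreads of the 4242 genes, of which 200 were changed. Of 67 genes changed by 1 on the log2 scale 65.7% were recovered. The share was 97.0% of 66 genes changed by 2 and 5.97% of 67 changed by 0.5. Of 124 genes called, 12 were among the 4042 unchanged ones, a larger share than the threshold aims for. In the real data 62.5% of the genes tested were called, a far larger share than was changed in the simulation. The simulated rates of recovery and of false calls therefore need not hold for the real fit. Alternatives were other pseudocounts (1 and 64), no filter on dim genes or a filter on 50%, quantile normalization, median centring, no variance trend, array weights, a replicate block, all probe sets, other probe sets of named genes and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.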

Results

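Gene expression was compared between air-liquid interface biofilm cells and bottom layer cells of the haploid yeast Saccharomyces cerevisiae strain that forms a floating film on ethanol medium. Per the labels, cells precultured for 24 h at 30°C were diluted 10-fold into 100 ml of medium with 4% ethanol in 250 ml beakers and stood for 48 h at 27°C. The film (called floaters in the labels) and then the settled cells under it (called sinkers) were aspirated from the beakers. Total RNA of each was measured on 3 arrays, 6 arrays in all, and the 2 groups give 1 comparison. The labels speak of triplicate beakers without tying an array to a beaker, so p-values measure the spread between these samples. Median signals of the 6 arrays lay between 128 and 151, and their means without the lowest and highest 2% of probe sets were all 500. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.18.

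Many genes for making ribosomes and amino acids were higher in the biofilm, and many stress and storage carbohydrate genes were lower. As lists these were called by camera with a preset correlation between genes, but with an estimated correlation camera called no list (lowest adjusted p = 0.178). Fry, which does not compare a list with other genes, called all 18 lists that camera called with the preset, in the same direction. Of the 12 genes with the largest rise in the biofilm, ADE4, which opens purine synthesis, was 8.66-fold higher, at 529 ± 8.44 signal units against 52.1 ± 29.1 (mean ± SD, n = 3 in each group). PRP43, an RNA helicase of splicing and ribosome assembly, was 7.48-fold higher, RNR1, the large subunit of ribonucleotide reductase, 7.20-fold, and MET14, a kinase of sulfate assimilation, 7.11-fold. The stationary phase gene SPG1 showed the largest fall, from 4017 ± 262 in the bottom layer to 49.1 ± 4.40 in the biofilm, 62.0-fold. SPI1, which encodes a cell wall protein, fell from 11782 ± 2704 to 228 ± 61.1, 48.7-fold.

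In the limma fit, 1613 of 4242 genes were higher in the biofilm and 1037 lower at an adjusted p below 0.05, and 1592 did not pass. At least 2-fold changes were seen for 821 of the higher and 552 of the lower genes. Changes of at least 8-fold were unequal between directions: among these named genes 1 was higher by that much, ADE4, and 48 were lower. In 2885 genes, 68.0% of those tested, all 3 arrays of one group lay above all 3 of the other, where chance gives 10%. The share of called genes that were higher, 60.9%, fell to 49.5% when each array was centred on its median, with 1310 genes higher and 1334 lower, since centring moved the median log2 fold change of all genes from 0.17 to -0.03.

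The remaining genes among the 12 largest rises were GRX8 (a glutaredoxin, 7.41-fold), RRB1 (ribosome assembly, 7.19-fold), SNL1 (7.11-fold), SER33 (serine synthesis, 7.01-fold), GUA1 (guanine nucleotide synthesis, 6.95-fold), MET10 (sulfite reductase, 6.81-fold), AIM20 (6.60-fold) and ASN1 (asparagine synthesis, 6.47-fold). Their adjusted p-values ran from 5.45e-07 for GUA1 to 3.49e-05 for SNL1. The remaining largest falls were YJR115W (29.6-fold), HBT1 (28.8-fold), SPL2 (27.3-fold), SLZ1, SIP18 (22.6-fold), HSP26 (22.5-fold), SSA4 (22.3-fold), RDN18-1 (18S ribosomal RNA, 19.5-fold), PHO89 (18.7-fold) and PHO84 (18.3-fold). The fold of RDN18-1 is that of a single probe set. The 5 control probe sets for 18S segments were brighter in the bottom layer by 0.62 to 4.26 on the log2 scale, with a mean of 4.31-fold. For SLZ1 the biofilm signal, 9.12 ± 3.30, was below the brightest unspiked control probe set on all 3 arrays, so its fall from 561 ± 85.7 was at least 16.6-fold. The biofilm signal of HBT1, 11.8 ± 5.95, was below it on 2 of 3 arrays, and the bottom layer signals of ADE4, PRP43 and SNL1 on 1 of 3, so the folds of these 4 genes and their order are uncertain. For dim genes the fold depends on the pseudocount: with 64 in place of 16 the log2 fold change was -5.17 for SPG1, -4.26 for YJR115W, -3.48 for HBT1, -3.64 for SPL2 (-5.50 with 1), -3.09 for SLZ1, 2.39 for ADE4, 2.24 for PRP43 and 2.20 for SNL1. With the ACT1 3' to 5' ratio as a covariate, an alternative chosen after seeing the data, it was 2.47 for ADE4 and -3.85 for SSA4.

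**Figure D1:**
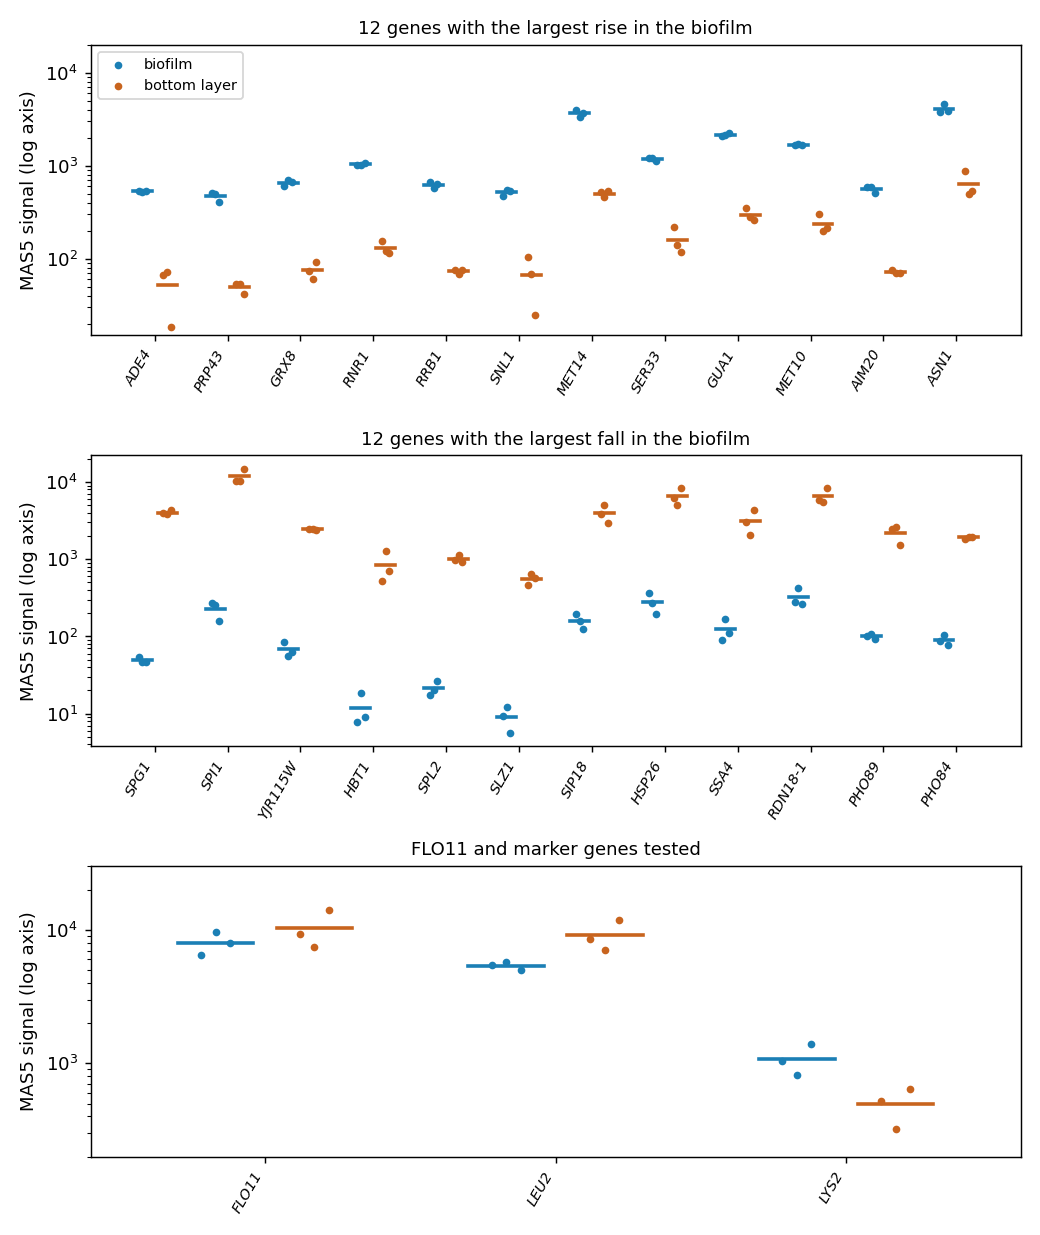
Signal of each array (points, logarithmic axis) and group mean (bars) for the 12 genes with the largest rise and the 12 with the largest fall in the biofilm, and for FLO11, LEU2 and LYS2, with biofilm arrays in blue and bottom layer arrays in orange. In the upper and middle panels the points of the groups do not overlap for any gene, while those of FLO11 do.

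Most genes for making ribosomes were higher in the biofilm. Of 45 ribosome biogenesis genes tested, 40 were higher, 2 lower and 3 did not pass, with a median log2 fold change of 1.53. RRB1 rose from 72.7 ± 3.60 to 623 ± 49.9, RRP5 (rRNA processing) from 171 ± 10.5 to 956 ± 9.72, RRP12 from 80.4 ± 12 to 501 ± 32.3 and UTP13 from 98.4 ± 8.69 to 560 ± 48.2. Of 138 cytosolic ribosomal protein genes only 81 were tested, since the others had no probe set paired with them alone or were dim. Among the 81, 58 were higher and none lower in the limma fit. The median of the 81 was 0.94, and RPS0A rose from 1308 ± 98.1 to 5023 ± 274 and RPL22B from 380 ± 61.2 to 1579 ± 50.8. Many of these genes are pairs of near-identical copies, so single members of the family are uncertain. Mitochondrial ribosomal protein genes were higher for 42 of 67, lower for 4, with a median of 0.66, and MRP13 rose from 172 ± 20.5 to 690 ± 42.3. Of 19 G1/S genes 13 were higher and 1 lower. RNR1 rose from 130 ± 21.3 to 1028 ± 25.7, POL12 (DNA polymerase alpha) from 76.8 ± 11 to 400 ± 31.7 and the G1 cyclin CLN1 from 58.7 ± 21.0 to 281 ± 24.1. Against all other genes (camera, preset correlation) the lists had adjusted p = 9.27e-09, 2.95e-07, 0.00162 and 0.0271 in that order. These calls were lost with an estimated correlation, where adjusted p = 0.178 for ribosome biogenesis, cytosolic ribosomal proteins and G1/S genes. For the mitochondrial list adjusted p = 0.305 there. The estimate for G1/S genes, -0.0466, was below the preset, so more correlation between genes does not account for that loss. The G1/S call was also lost without the dimmest 50% of genes, with adjusted p = 0.554.

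Most genes of amino acid synthesis and sulfur use were likewise higher in the biofilm. Of 21 sulfur and methionine genes 18 were higher and 3 did not pass, with a median log2 fold change of 1.85. MET14 rose from 499 ± 39.1 to 3648 ± 288, MET10 from 236 ± 54.9 to 1676 ± 34.2, MET16 (reduction of activated sulfate) from 150 ± 28.8 to 1020 ± 83.2 and the sulfate permease gene SUL1 from 451 ± 38.3 to 1969 ± 130. Of 46 amino acid synthesis genes 34 were higher, 5 lower and 7 did not pass, with a median of 1.11. HIS1 (histidine) rose from 548 ± 75.2 to 2606 ± 292, HOM3 (threonine and methionine) from 235 ± 48.3 to 1326 ± 125 and ASN1 from 634 ± 208 to 4075 ± 438. The camera test gave adjusted p = 1.79e-05 for the sulfur list and adjusted p = 0.000128 for the amino acid list, and adjusted p = 0.178 for both with an estimated correlation.

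Most stress and storage carbohydrate genes and most phosphate starvation genes were lower in the biofilm, that is higher in the bottom layer. Of 34 environmental stress response genes 27 were lower, 1 was higher and 6 did not pass, with a median log2 fold change of -1.39. Beside SPI1, these included SIP18, which fell from 3987 ± 1053 to 159 ± 33.5, the small heat shock protein gene HSP26, from 6555 ± 1730 to 277 ± 81.9, and the transcriptional repressor gene XBP1, from 775 ± 63.5 to 36.9 ± 14.8 (log2 fold change -3.94, and -3.06 with 64 as the pseudocount). Of 19 trehalose and glycogen genes 14 were lower and 1 was higher. The trehalose synthesis genes TSL1 and TPS1 fell from 1426 ± 295 to 385 ± 51.1 and from 6051 ± 1213 to 1900 ± 226, and so did NTH2, which breaks trehalose down, from 1810 ± 551 to 282 ± 15.1. Of 14 phosphate starvation genes 9 were lower and 4 higher. The phosphate transporter genes PHO84 and PHO89 fell from 1919 ± 65.4 to 90.4 ± 14.6 and from 2210 ± 588 to 100.1 ± 7.34, and SPL2 from 1002 ± 110 to 21.4 ± 4.58. The acid phosphatase gene PHO3 rose from 1468 ± 222 to 3708 ± 786. It is also among the thiamine synthesis genes of the closing section, so what its rise reflects is uncertain. Of 22 autophagy and vacuolar protease genes 7 were lower, 3 higher and 12 did not pass. The protease gene PRB1 fell from 3449 ± 739 to 350 ± 52.9 and ATG8 from 4328 ± 269 to 773 ± 112. Camera gave adjusted p = 9.53e-10 for stress, adjusted p = 3.96e-05 for trehalose and glycogen, adjusted p = 0.0213 for phosphate and adjusted p = 0.0329 for autophagy. With an estimated correlation these were adjusted p = 0.178, 0.254, 0.254 and 0.256. The autophagy call was also lost under quantile normalization (adjusted p = 0.0539), with array weights (0.0520), without bottom replicate 3 (0.0697) and with the ACT1 covariate (0.0983). Both the phosphate and the autophagy call were lost without the dimmest 50% of genes, with adjusted p = 0.0932 and 0.0755.

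In 5 lists for the use of carbon and nitrogen sources more genes were lower in the biofilm than higher. Of 25 ethanol use and gluconeogenesis genes 15 were lower, 9 did not pass and 1, the acetaldehyde dehydrogenase gene ALD5, was higher. The acetate transporter gene ADY2 fell from 6230 ± 921 to 1000.1 ± 224, the carnitine carrier gene CRC1 from 11335 ± 1917 to 3091 ± 61.0 and the acetyl-CoA synthetase gene ACS1 from 13188 ± 2793 to 3179 ± 558. Of 38 respiratory chain genes 19 were lower and 19 did not pass. Among the former were CYC7, an isoform of cytochrome c, from 1537 ± 345 to 139 ± 43.1, NDE2, an NADH dehydrogenase gene, from 4999 ± 514 to 1503 ± 108, and RIP1 of complex III, from 4488 ± 1447 to 1126 ± 277. Peroxisome and beta-oxidation genes were lower for 12 of 21 and higher for 1. POT1 (thiolase) fell from 7874 ± 1212 to 1118 ± 86.9 and the catalase gene CTA1 from 5102 ± 492 to 1668 ± 185. Of 24 nitrogen catabolite genes 11 were lower and 4 higher, with the proline use genes PUT1, from 4336 ± 872 to 397 ± 52.9, and PUT4, from 13447 ± 4893 to 2535 ± 345, among the lower. Of 19 glycolysis and fermentation genes 8 were lower, 10 did not pass and 1, the hexokinase gene HXK2, was higher, at 900.5 ± 90.6 against 307 ± 40.5. Camera gave adjusted p = 3.39e-05, 4.11e-05, 0.000128, 0.0147 and 0.0341 for the 5 lists in that order, and adjusted p = 0.264, 0.178, 0.178, 0.178 and 0.264 with an estimated correlation. The glycolysis call was also lost under quantile normalization (adjusted p = 0.0950), without biofilm replicate 1 (0.0504), bottom replicate 1 (0.0535) or bottom replicate 3 (0.0697), without a filter on dim genes (0.0685) and without the dimmest 50% (0.0824). It was lost as well with the ACT1 covariate (adjusted p = 0.202) and with genes kept by the unspiked controls (0.0579), both chosen after seeing the data.

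FLO11, the adhesin gene that flor film formation is known to need, was bright in both groups and did not pass the test. Its signal was 7988 ± 1545 in the biofilm and 10266 ± 3409 in the bottom layer, a log2 fold change of -0.33 (SE 0.26, adjusted p = 0.283). Of the 4 flocculin genes tested the other 3 were lower in the biofilm: FIG2 at 95.6 ± 19.2 against 389 ± 20.4, FLO10 at 150.0 ± 20.8 against 291 ± 28.8 and AGA1 at 84.6 ± 22.6 against 146 ± 15.8. The call of AGA1 was lost without biofilm replicate 2 (log2 fold change -0.50, adjusted p = 0.0522). FLO10 has 6 other, dimmer probe sets: 2 lay below the unspiked controls on all 3 arrays of at least 1 group and are set aside, and the other 4 were lower in the biofilm mean, of which 1 passed. The flocculin list had adjusted p = 0.0341 with camera and adjusted p = 0.264 with an estimated correlation. The call was lost under quantile normalization, with adjusted p = 0.0664, under median centring, with adjusted p = 0.0581, without bottom replicate 3, with adjusted p = 0.0703, and with the ACT1 covariate, with adjusted p = 0.132. Among 14 regulators of FLO11, 5 were higher and 8 lower, and the list was not called (adjusted p = 0.161, but 0.0473 with genes kept by the unspiked controls). The sensor gene MSB2 rose from 246 ± 41.2 to 1018 ± 113, while the transcription factor gene TEC1 fell from 1471 ± 422 to 460 ± 53.5, the kinase gene SNF1 from 273 ± 46.4 to 82.0 ± 19.4 and GPA2 from 1563 ± 289 to 667 ± 63.2.

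Most of the tested genes that yeast is known to raise when oxygen is short were lower in the biofilm than in the bottom layer. Of 12 hypoxic genes 8 were lower and 4 did not pass, with a median log2 fold change of -1.52. The fatty acid desaturase gene OLE1 fell from 3081 ± 599 to 555 ± 63.4, CYC7 with a log2 fold change of -3.34, the cell wall mannoprotein gene TIR4 from 942 ± 157 to 166 ± 22.8 and the sterol esterification gene ARE1 from 1881 ± 159 to 608 ± 34.1. All 10 seripauperin genes tested were lower, with a median of -0.78. PAU10 fell from 342 ± 21.6 to 96.3 ± 6.06, but these genes are nearly identical in sequence, so the 10 are not separate measurements. Camera gave adjusted p = 0.000296 for hypoxic genes and adjusted p = 0.000358 for seripauperins, and adjusted p = 0.178 and 0.187 with an estimated correlation. The estimate for hypoxic genes, -0.0663, was below the preset, so more correlation between genes does not account for that loss. The seripauperin call was lost without the dimmest 50% of genes, with adjusted p = 0.0569. The ergosterol synthesis list, whose pathway uses oxygen, was not called (adjusted p = 0.233), with 14 of 25 genes higher and 3 lower. ERG20 rose from 1500 ± 103 to 3625 ± 182 and ERG6 from 937 ± 142 to 2314 ± 102.

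**Figure D2:**
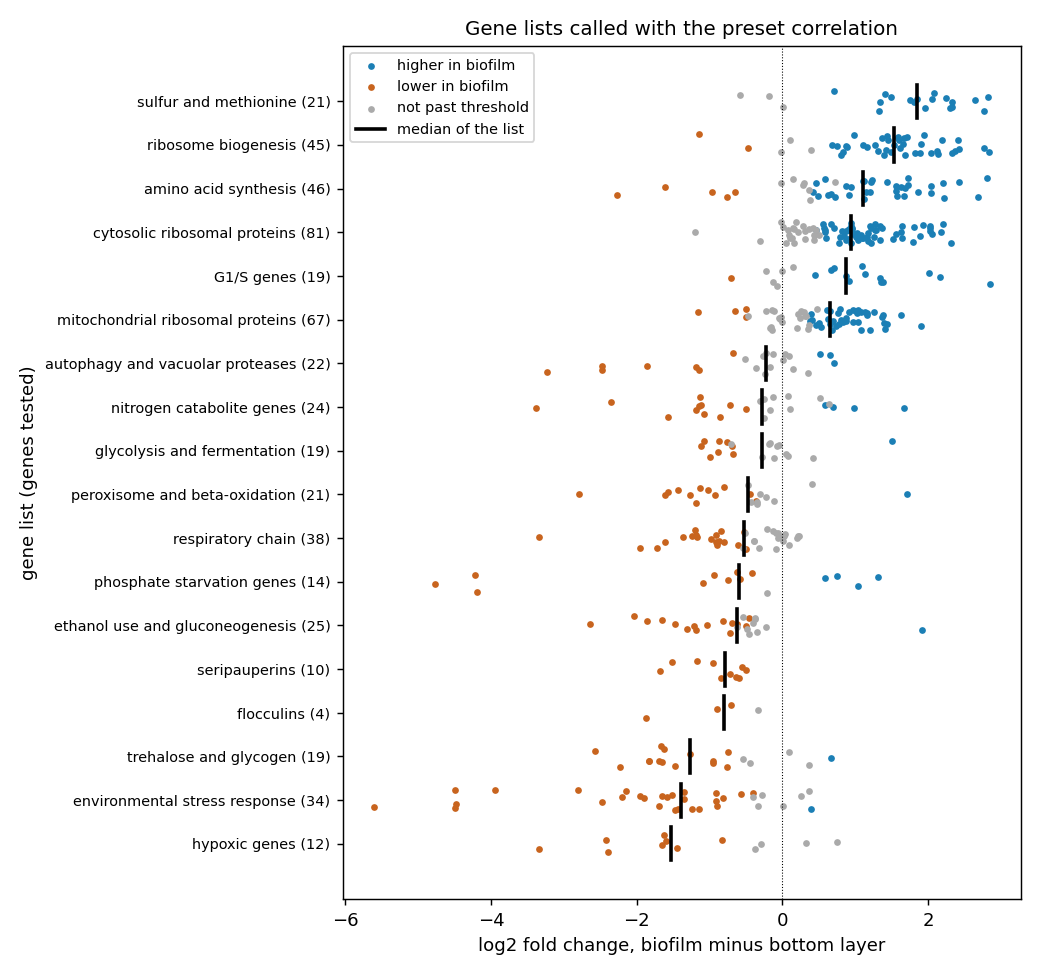
Log2 fold change (biofilm minus bottom layer) of each gene tested in the 18 lists called with the preset correlation, as points coloured by the limma result, with the list median as a black bar and the number of genes tested after each name. Medians run from -1.52 for hypoxic genes to 1.85 for sulfur and methionine genes; none of the 18 was called with an estimated correlation.

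The other 13 lists tested were not called by camera and mostly held genes going both ways. Fry called 9 lists that camera did not. Higher by fry were lysine synthesis (adjusted p = 0.000786), ergosterol synthesis (0.00168), cell separation (0.00324), TCA cycle (0.00790) and phospholipid synthesis (0.0262). Lower by fry were hexose transporters (adjusted p = 0.00104), pheromone response and haploid genes (0.00426), oxidant defence (0.00808) and FLO11 regulators (0.0101). Hexose transporter genes were lower for 5 of 9 and higher for 1 (adjusted p = 0.0525, but 0.0264 with array weights and 0.0387, 0.0297 and 0.0456 without biofilm replicate 2, bottom replicate 2 and bottom replicate 3), with GAL2 at 42.0 ± 5.39 in the biofilm against 493 ± 120 and HXT1 at 59.8 ± 20.5 against 466 ± 65.7. With 64 as the pseudocount their log2 fold changes were -2.37 and -2.10 in place of -3.11 and -2.69. Oxidant defence genes were higher for 7 and lower for 13 of 34 (adjusted p = 0.126): the glutathione synthesis gene GSH2 rose from 177 ± 22.0 to 998 ± 23.9 and ZWF1, of the pentose phosphate pathway, fell from 3774 ± 508 to 539 ± 112. Lysine synthesis genes were higher for 5 of 7 and lower for 2 (adjusted p = 0.333). TCA cycle genes were higher for 7 and lower for 3 of 19 (adjusted p = 0.707), fatty acid synthesis genes higher for 7 and lower for 4 of 17 (adjusted p = 0.978), and phospholipid synthesis genes higher for 6 and lower for 3 of 17 (adjusted p = 0.707). In the iron regulon 8 of 22 genes were higher and 5 lower (adjusted p = 0.973), and in the zinc regulon 4 of 9 were higher and 3 lower (adjusted p = 0.861). For cell wall genes 9 of 31 were higher and 6 lower (adjusted p = 0.510), with the glucanase gene EXG1 rising from 543 ± 52.1 to 2842 ± 301. For cell separation genes 5 of 10 were higher and 2 lower (adjusted p = 0.498), with DSE4 rising from 108 ± 30.8 to 597 ± 101 and CTS1 falling from 708 ± 313 to 216 ± 23.1. Of 32 proteasome genes 7 were higher and 4 lower (adjusted p = 0.899), with a median and mean above 0 (0.22 and 0.06) but a test direction below that of other genes. Histone genes were lower for 1 of 4 (adjusted p = 0.652), and HTB1 passed as higher under quantile normalization (log2 fold change 0.33, adjusted p = 0.0462) and with array weights (0.32, adjusted p = 0.0287) only. Pheromone response and haploid genes were lower for 6 and higher for 2 of 13 (adjusted p = 0.0994).

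The alpha-specific genes, which only cells of the alpha mating type are known to express, were above the unspiked controls on all 6 arrays. The a-specific genes were dim. Among the alpha-specific genes MF(ALPHA)2 had the lowest signal, at 152 ± 7.08 in the biofilm and 263 ± 52.3 in the bottom layer. Of the 5 alpha-specific genes 2 were higher and 2 lower in the biofilm (list adjusted p = 0.591). MF(ALPHA)1, a pheromone gene, was at 3271 ± 281 in the biofilm and 1509 ± 438 in the bottom layer, STE3, the receptor gene, at 1907 ± 266 and 1121 ± 56.7, and the agglutinin gene SAG1 at 376 ± 83.9 and 1704 ± 433. The 7 a-specific genes fell into the dimmest 25% and were not tested. No a-specific gene lay above all unspiked control probe sets on all 3 biofilm arrays, and 1 did on all 3 bottom arrays, the pheromone gene MFA1, at 13 ± 5.72 in the biofilm and 116 ± 7.54 in the bottom layer. Without biofilm replicate 3, whose control signal was the highest of its group, AGA2 and STE6 were above the controls on the other 2 biofilm arrays, and without bottom replicate 3 the other a-factor gene, MFA2, was above them with MFA1, so these counts turn on single arrays. These 4 genes were singled out after their values were seen. The labels give the strain as MATa. Of 25 meiosis and sporulation genes 2 were tested, which is too few for a list test: NDT80 was lower in the biofilm, at 99.5 ± 57.1 against 243 ± 13.8, and GAS2 did not pass, at 118 ± 28.0 against 109 ± 34.1.

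**Figure D3:**
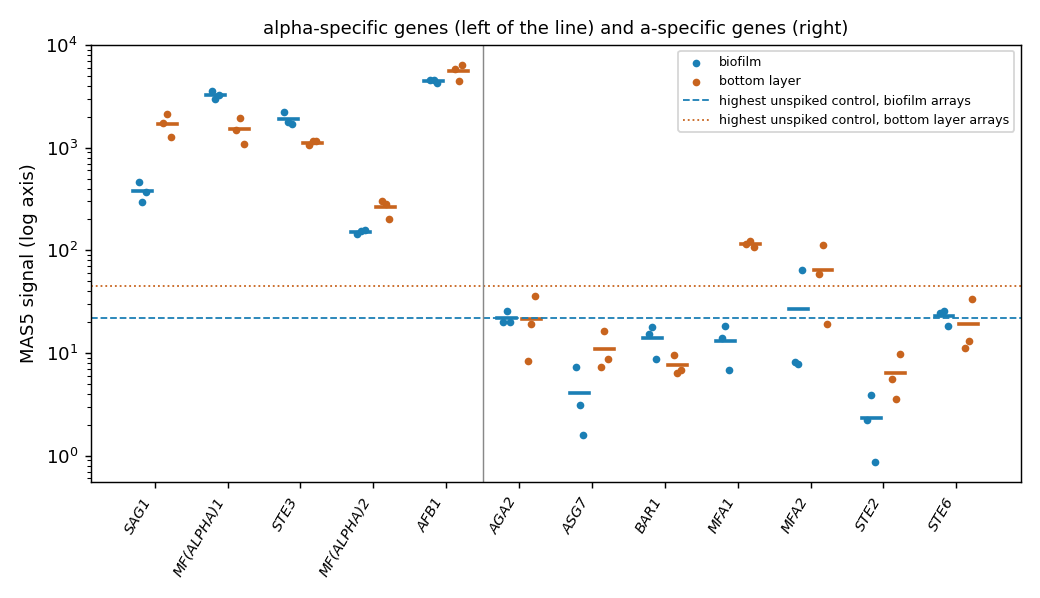
Signal of each array (points, logarithmic axis) and group mean (bars) for the 5 alpha-specific and 7 a-specific genes; the dashed and dotted lines mark the highest unspiked control signal among biofilm arrays (21.9) and among bottom layer arrays (44.8). The alpha-specific genes lie above both lines, and the a-specific genes lie mostly below the dotted line, with MFA1 above it on the 3 bottom arrays.

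The strain's marker genes were read as a check of the labels, which give leu2 as a deletion and list lys2 and ura3 mutations. Leucine, histidine and uracil are the supplements they name for the medium, and whether it held lysine is not given in the sources used here, so what LYS2 and lysine synthesis values reflect is uncertain. LEU2 was bright, at 5372 ± 380 in the biofilm and 9133 ± 2435 in the bottom layer (log2 fold change -0.73, SE 0.21, adjusted p = 0.0109). Of its other probe sets 1 was bright too, at 908 ± 308 and 2075 ± 397 (log2 fold change -1.22), and 1 lay below the unspiked controls on all 6 arrays, at 11.4 ± 5.66 and 9.89 ± 3.69. LYS2 was higher in the biofilm, at 1084 ± 289 against 496 ± 159 (log2 fold change 1.12, SE 0.26, adjusted p = 0.00313). URA3 was among the dim genes not tested, at 30.3 ± 3.46 and 16.3 ± 1.02. A probe set outside a deleted or mutated part checks nothing, and the probe positions are not given in the sources used here.

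The 6 arrays separated by group, and some control probe sets moved with the groups. The first principal component held 85.6% of the variance and the second 6.63%, and correlations across genes were 0.960 to 0.981 within groups and 0.732 to 0.804 between them. Ribosomal RNA control probe sets were brighter in the bottom layer, by 2.11 on the log2 scale for 18S and 1.48 for 25S (exact two-sided permutation test, p = 0.1 for each, the smallest p that 3 against 3 allows). The ratio of the 3' to the 5' ACT1 control, a sign of RNA integrity, was 1.54, 2.04 and 1.56 in the biofilm and 2.36, 1.80 and 3.84 in the bottom layer (exact permutation p = 0.2). The same ratio of SPT15 went the other way (log2 difference -0.61, exact permutation p = 0.3). It was high on all arrays, at 6.48, 11.9 and 12.9 in the biofilm and 7.15, 4.52 and 8.69 in the bottom layer. Bottom replicate 3 stood apart, with the highest unspiked control signal (44.8, against 16.3 to 21.9 on the other arrays) and the highest ACT1 ratio; without it 1583 genes were higher and 1080 lower.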

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

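The tests of 18S segments, of hybridisation controls and of the small nucleolar RNA list below were chosen after the results were seen. Signals were found in probe sets that the comparison of genes does not use. Control probe sets for 18S ribosomal RNA were brighter in the bottom layer by 2.11 on the log2 scale, 4.31-fold, and those for 25S by 1.48, 2.79-fold. The 5 segments of 18S differed by 0.62, 1.03, 1.45, 3.18 and 4.26. Whether 18S was more intact in the bottom layer remains open. The segments spread over 3.63, where the largest SD among arrays was 0.51, but a difference in integrity can itself move segments unequally, so this spread excludes nothing. If dimmer labelled samples had been scaled up, hybridisation controls would rise with ribosomal RNA; they rose by 0.90 in the bottom layer against 2.11 for 18S, and without bottom replicate 3 by 0.37 against 1.97. For 25S this stays open, since its rise exceeded that of the controls by 0.58, within the sum of their standard errors (0.83). Without bottom replicate 3 the rise of 25S was 1.28 against 0.37 for the controls, a gap beyond that sum, so the answer turns on that array. A general rise of non-coding RNA in the bottom layer remains open: 14 of 36 small nucleolar RNA genes were lower in the biofilm and 4 higher, with a median log2 fold change of -0.38 against 0.17 for all genes, and adjusted p = 0.0130 with the preset correlation, but adjusted p = 0.606 with an estimated one, and the median of 87 transfer RNA genes was -0.03.

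Probe sets without a gene in the platform table were a further signal outside the comparison. Of 1141 that were bright enough to test, 108 were higher in the biofilm and 409 lower. Probe set 3994_at, at 1769 in the biofilm and 33.0 in the bottom layer, rose more than any named gene (log2 fold change 5.15). It was picked after its values were seen. What these measure is not given in the sources used here.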

How the results depend on the processing

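The settings with the ACT1 ratio as a covariate and with genes kept by the unspiked controls, and all settings for the principal components, were chosen after seeing the data; the one with unspiked controls was reshaped because its first form removed no genes. No gene called higher was called lower, or the reverse, in the settings with 1 probe set per gene. Leaving out 1 array gave 1450 to 1592 genes higher, 926 to 1080 lower, 16 to 19 lists called and 85.4% to 89.2% of variance on the first component. With all probe sets, 6956 tested, 2015 were higher and 1808 lower, a share higher of 52.7% in place of 60.9%; probe sets of no listed gene were mostly lower among those called. The first component held 80.6% there; it held 82.9% without the filter on dim genes and 84.0% with genes kept by the unspiked controls. With an estimated correlation 0 lists were called. Same-numbered arrays were not treated as pairs in the main fit, because the labels do not tie a replicate number to a beaker. Their deviations within the groups had correlations of -0.013, -0.093 and 0.163, not all above 0.1. Whether they share beakers stays open. The replicate block gave 1590 higher, 1046 lower and 18 lists, and 1 of 3 biofilm replicates correlated best with its own number. Some results near 0 changed direction, and the cause was not tested. The fatty acid synthesis list did so with array weights (adjusted p = 0.995), with the ACT1 covariate (0.807) and without biofilm replicate 1 or bottom replicate 3 (0.869 to 0.992 over all arrays left out in turn), the iron regulon without the dim filter (0.895), with array weights (0.995) and without biofilm replicate 2 (0.746 to 0.969 over all arrays left out), and the proteasome without the dim filter (0.933) and with fry (0.127). The log2 fold change of FLO11 was 0.18 with the ACT1 covariate (adjusted p = 0.319). GAS2 gave -0.0906 with median centring and -0.0641 with the ACT1 covariate. With an array left out GAS2 ranged from -0.0218 to 0.324, HTB2 from -0.431 to 0.0585 and HTZ1 from -0.171 to 0.107. Other probe sets gave 0.0715 for LEU2, where the signal was below the unspiked controls, and 0.26 for FLO10, where it was below them in the bottom layer, so neither is a measurement. With a pseudocount of 1 HBT1 and SLZ1 fell under the filter, as did other dim named genes without the dimmest 50%, so these gave no value. Signal over background limits dim genes: the dimmest gene tested had a mean of 97.5.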

Other observations

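The 8 further gene lists here, and the tests of other splits, of RNA degradation with the ACT1 covariate and of mating type, were chosen after the results were seen. Most genes that load amino acids onto transfer RNA were higher in the biofilm, as were most of those for making ribosomes. Of 22 aminoacyl-tRNA synthetase genes 20 were higher and 2 did not pass, with a median log2 fold change of 1.71 (adjusted p = 1.18e-06 with camera, adjusted p = 0.219 with an estimated correlation); HTS1 (histidine) rose from 338 ± 61.8 to 2154 ± 336 and DED81 (asparagine) from 845 ± 77.5 to 3855 ± 168. Purine and pyrimidine synthesis genes were higher for 23 of 27 and lower for 1, with a median of 1.18 (adjusted p = 2.10e-05, and adjusted p = 0.124 with an estimated correlation); IMD4 (guanine nucleotides) rose from 400.5 ± 80.5 to 2287 ± 183 and URA5 (pyrimidines) from 1078 ± 94.8 to 4265 ± 393. Translation factor genes were higher for 18 of 27 and lower for 2 (adjusted p = 0.00446, and adjusted p = 0.552 with an estimated correlation), with TEF4 rising from 316 ± 64.8 to 1969 ± 333.

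Most genes known from stationary phase cultures were lower in the biofilm: of 12 tested 10 were lower and 1 higher, with a median of -2.73 (adjusted p = 5.83e-06, and adjusted p = 0.124 with an estimated correlation). Beside SPG1, the chaperone gene SSA3 fell from 812 ± 137 to 61.3 ± 6.53 and FMP45 from 472 ± 153 to 40.5 ± 7. Amino acid permease genes went both ways, 6 higher and 9 lower of 19 (adjusted p = 0.180): BAP3 rose from 172 ± 60.2 to 1084 ± 66.2 while GNP1 fell from 2261 ± 548 to 561 ± 105. Of 9 thiamine synthesis genes 4 were higher and 2 lower (adjusted p = 0.705), with THI4 falling from 3150 ± 945 to 289 ± 25.9. Transfer RNA genes were higher for 15 and lower for 17 of 87 (adjusted p = 0.0848). Adjusted over the list alone, 6 thiamine genes were higher, 10 transfer RNA genes higher and 15 lower, and 12 small nucleolar RNA genes lower.

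Most genes differed between the groups, and technical causes were weighed against a difference between the cells. Of the 10 splits of the 6 arrays into 3 and 3 only 1, the real one, called genes (2650 against at most 0 for the others), and 10 splits are too few for a share under 0.05. The other splits mix the groups, so the difference between the groups counts as spread in them and leaves little room for calls. Their counts therefore say nothing about technical causes. If degraded RNA in the bottom layer made the changes, they should shrink with the ACT1 ratio as a covariate. The median change of the called genes was 1.02 times that without it. The ACT1 ratio overlapped between the groups, so as a covariate it can take up little of a difference between them. The SPT15 ratio went the other way, and degradation stays open. If array scaling made them, calls should be lost under median centring or quantile normalization, and 81.2% or more kept their call. Both bring the arrays to a common level, so neither can show a shift shared by most genes. Scaling to the hybridisation controls, brighter by 0.90 on the log2 scale in the bottom layer, was not tried, so scaling stays open in that respect. Handling that differed between film and settled cells goes with the groups and stays open.

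The strain is labelled MATa, and the signals of the alpha-specific genes were weighed against that label. All 5 of 5 alpha-specific genes were above the unspiked controls on all 6 arrays, which the alpha mating type would give. Cells of an a/alpha diploid would lack haploid-specific RNA, and 6 of 6 haploid-specific genes were above the controls on all 6 arrays. This bar is low: per array only 3.93% to 11.5% of genes lay below the controls. Counts of genes above the controls therefore cannot by themselves decide for the alpha mating type or against a diploid. A mixture with MATa cells remains open in both groups. In the bottom layer 1 of 7 a-specific genes, MFA1, was above the controls on the 3 arrays, and MFA2 was too on the other 2 without bottom replicate 3. In the biofilm none was on all 3 arrays, but AGA2 and STE6 were on the other 2 without biofilm replicate 3. The alpha-specific signals, the lowest 152 ± 7.08 in the biofilm and 263 ± 52.3 in the bottom layer, go against cells that were all MATa, as labelled. The receptor gene STE2 of such cells lay below the controls on all 6 arrays.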
